A study of Mus musculus with 9 samples.

How the data were processed

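Genomic DNA of 8 iPSC lines and 1 ESC line was hybridised against reference DNA on 9 NimbleGen whole-genome tiling arrays for mouse build mm9. Per the labels' protocols, cells were grown on feeder cells, moved to gelatin before DNA preparation and extracted with a Qiagen kit. Groups were taken from the sample titles: 2 4N-positive and 6 4N-negative iPSC lines, and 1 H2A.X-null ESC line. The origin of a line (PF, TTF or Bcell) is part of its name. The replicate numbers name lines and pair nothing, since each line is a sample of its own. P-values of the group comparisons measure the spread between lines with 1 array each, in which line, culture and array differences are mixed. Those of the gene lists rest on shifts of calls along the genome, and that of the chromosome medians of Bcell2 and Bcell4 on permuted chromosomes. Neither kind measures the spread between lines.

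Per the file headers, each deposited array table holds the log2 signal of both channels as scanned, after a spatial correction and after normalization between channels, and the log2 ratio of EXP over REF at each stage. The corrected log2 ratio as deposited was used, and it equalled the series value table on every probe of every array. The medians of the deposited columns were -0.01 on PF1, 0.02 on the array labelled TTF1, -0.01 on PF2, 0.00 on TTF2, 0.00 on TTF3, 0.01 on Bcell2, 0.00 on Bcell3, 0.01 on Bcell4 and 0.00 on the array labelled H2A.X-null. The scale and the centring (mean 0) of that table are known from this match and its direction is not, while the method of the spatial correction and of the normalization is not given in the sources used here. The deposited tables also give the GC content of each probe as a fraction per the file headers, which was not used, since GC content was counted in the genome over 100 kb around each probe. Direction is likely and not settled: per the labels the test DNA carried Cy5 and the reference Cy3, whereas per the file headers the EXP column was scanned at 532 nm, where Cy3 is read, and the REF column at 635 nm. EXP was taken as the test DNA because column names and sample descriptions put the line over ESC, because the J to D part of Igh was low on all Bcell arrays, and because the Y chromosome was low on only some arrays although the labels give them 1 reference. No array was turned, and the lowest correlation between any 2 arrays over all probes was -0.04. Raw median log2 signals ran from 12.30 to 12.79 in the EXP channel and from 11.49 to 12.60 in the REF channel. Array position data in the files put PF1 and PF2 on slide 1, the arrays labelled TTF1, TTF3 and H2A.X-null on slide 2, the 3 Bcell arrays on slide 3 and TTF2 on slide 4.

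Log2 ratios were centred on the median of the 664420 autosomal probes of each array. Each chromosome was divided by penalised least-squares changepoint segmentation (penalty 25 times the noise variance, noise from differences of neighbouring probes, values limited to 3 noise SDs around a running median of 11 probes). A segment was called at 10 or more probes and a mean at or beyond 0.25 or -0.25. A whole chromosome was called at a median at or beyond 0.15 or -0.15. Calls of the iPSC arrays were merged where they overlapped by at least 50% of the shorter. Chromosome lengths of the array design equalled those of the mm9 genome used here, except for Y_random, which the genome used here does not hold. Genes came from the GENCODE vM1 annotation (22380 protein-coding genes).

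Segment counts, called length and the mean over each of 6 antigen receptor loci were compared by exact two-sided permutation tests of the difference of means, counting splits with an absolute difference as large. With 28 splits of 2 against 6 the smallest p is 0.0357, and with 56 splits of 3 against 5 it is 0.0179, lower than foreseen before the data were examined. Medians of 100 kb bins with at least 10 probes were compared with limma (lmFit and eBayes) and Benjamini-Hochberg adjustment at 0.05. Overlap of 11 gene lists with calls was tested by 10000 circular shifts. The lists were pluripotency and reprogramming, trophoblast and extraembryonic, imprinted, DNA damage response and tumour suppressors, histone and DNA modifying, fibroblast, B cell, copy number variable families, olfactory receptors, vomeronasal receptors and zinc finger proteins. Groups, tests, lists and most alternatives were fixed before the data were examined. The software was Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, numba 0.67.0, statsmodels 0.14.6, matplotlib 3.10.9, R 4.3.3 and limma 3.58.1.

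Segmentation, limma on bins and the list shifts were tested on simulated data, and the exact permutation tests were not. For segmentation and limma the noise was drawn as independent normal values, without waves or outlying probes. For limma the spreads of the most variable bins were left out. The rates below therefore hold for such noise and need not hold on these arrays. Segments of size 0.6 were all found at the lowest and the highest noise (0.118 and 0.209), and those of size 0.3 over 30 probes in 99.0% and 85.3%, with at most 1 false call. For the 4N comparison limma recovered 66% of changed bins of size 0.3 and 98% of size 0.6 with 8 false calls among 23980 bins, and for the Bcell comparison 80% and 99% with 7. Of 200 random lists of 38 positions, 4% had a shift p under 0.05. The positions were drawn independently and the simulated segments held equal numbers of probes. Families of neighbouring genes and calls of unequal length were not simulated, so this rate need not hold for the lists used here.

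The regions named in the text were chosen by a rule: whole chromosomes past the limit, per line the 3 called autosomal segments with the largest absolute mean and the 3 with most probes, the 5 merged regions called in most lines, up to 10 calls of the H2A.X-null array, the 6 receptor loci and H2afx. Genes were those of the lists that overlap a call, and up to 3 other protein-coding genes per region in coordinate order, without Gm and Rik symbols. Not every region that the rule gives is printed. Alternatives were the series value table, loess on intensity, normexp background correction (offset 50), segment limits of 0.5 and 0.15, 5 or 20 probes, penalty 50, runs of bins, removal of a GC trend, other bin sizes and summaries, robust eBayes, slide or origin as a block, removal of the 10% dimmest probes, and leaving out each line. Fits without the arrays labelled TTF1 and TTF3, or TTF1 and TTF2, were added after the data were seen, as were other scalings of the J to D interval and of the probe beside H2afx. The reads of the probes beside H2afx were not tested as a group comparison, and segments on Y_random were left out of the autosomal counts.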

Results

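Copy number was measured in 9 mouse stem cell DNA samples by array comparative genomic hybridisation, in which test DNA and reference DNA carry different dyes and compete for the same probes. Of these, 8 were induced pluripotent stem cell (iPSC) lines, which are differentiated cells returned to a state like that of embryonic stem cells (ESC), and 1 was an ESC line without H2A.X, the histone variant that is phosphorylated beside DNA double-strand breaks. The labels call 2 iPSC lines 4N-positive (PF1 and TTF1) and 6 4N-negative (PF2, TTF2, TTF3, Bcell2, Bcell3 and Bcell4). In this field 4N refers to tetraploid complementation, a test of whether injected stem cells can form the whole embryo. PF and TTF are used here as names only. The labels give the iPSC arrays a male ESC reference of mixed 129Sv/C57 background and the H2A.X-null array a floxed ESC reference of 129/Sv background. Each array held 713358 probes, 664420 of them autosomal, at a median spacing of 3530 bp in build mm9. There was 1 array per line and no repeat array, so a call on an array has no replicate check, and the number of arrays limits the precision of every group comparison. The probe-to-probe noise (SD) ran from 0.118 on the array labelled TTF1 to 0.209 on TTF2.

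H2afx, the gene of H2A.X (ENSMUSG00000049932.2), lies on chromosome 9 from 44142798 to 44144154 on the plus strand. No probe lies inside it. The nearest probe, at 44142495, is 303 bp upstream of the gene. Values are log2 ratios of the EXP over the REF channel, and EXP as the test DNA is the likely direction, because the column names and the sample descriptions put the line first while the dyes in the labels and the scan wavelengths in the file headers disagree. The log2 ratio of this probe was 0.05 on PF1, -2.54 on the array labelled TTF1, -0.18 on PF2, -0.22 on TTF2, 0.03 on TTF3, 0.29 on Bcell2, 0.00 on Bcell3, -0.02 on Bcell4 and 0.06 on the array labelled H2A.X-null. On the array labelled TTF1, 5 of the 664420 autosomal probes were as low, and the next probe upstream, inside Dpagt1, read -0.27. With normexp background correction, added after the data were seen, the probe beside H2afx read -0.89 on the array labelled TTF1, still the lowest of the 9 arrays, and 1.26 on Bcell2, 1.04 on Bcell4 and 0.51 on Bcell3. The deleted part of H2afx is not given in the sources used here, and a probe outside it would check nothing. The titles of all 9 samples begin with H2AX, those of the iPSC lines included, and the sources used here do not say whether any iPSC line was made from H2A.X-targeted cells. Because the low value stood on an iPSC array and not on the array labelled H2A.X-null, both are called by their labels throughout, and directions drawn from either rest on those labels.

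**Figure D1:**
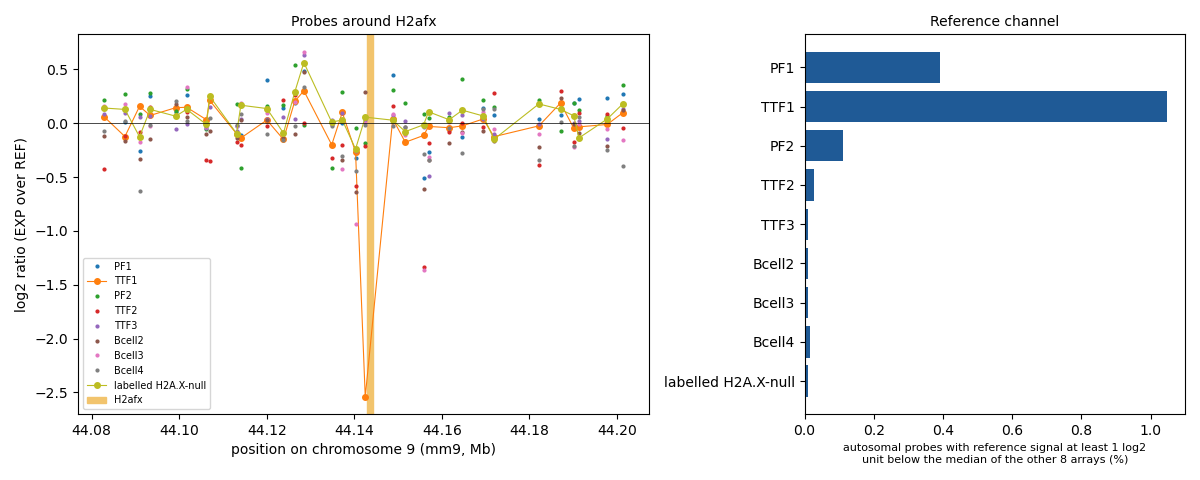
Left, log2 ratio of the probes around H2afx on each of the 9 arrays against position on chromosome 9 in Mb, with the gene shaded. The array labelled TTF1 reads -2.54 at the probe beside the gene and the array labelled H2A.X-null 0.06. Right, bars give the percentage of autosomal probes whose reference signal lies at least 1 log2 unit below the median of the other 8 arrays, 1.05% for the array labelled TTF1. In the test channel of that array, which is not drawn, the percentage was 0.90%.

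The first question was which chromosome regions each line had gained or lost against the reference DNA. PF1 gained most of chromosome 11. Its 3 segments with most probes ran from 93541925 to 107509266 (log2 ratio 0.45 ± 0.21, SD over 3943 probes), from 82348621 to 90614012 (0.39 ± 0.18) and from 48441504 to 55459836 (0.35 ± 0.16), and the first of them held Stat3, the transducer of LIF signalling, Brca1, a DNA repair gene, and Col1a1. Trp53, which encodes p53, lay in a chromosome 11 gain of 0.35 on PF1, and Suz12, a subunit of Polycomb repressive complex 2, in a gain of 0.44. TTF2 gained chromosome 6 from 52811010 to 90491755 (0.38 ± 0.24, 37.7 Mb) and chromosome 1 from 114871427 to 148728244 (0.34 ± 0.23, 33.9 Mb). Bcell3 carried 4 gains on chromosome 1 between 100799071 and 160543176, with means of 0.33 to 0.42. The chromosome 1 gains of TTF2 and Bcell3 both held Nr5a2, a nuclear receptor that can take the place of Oct4 in reprogramming, Kdm5b, an H3K4 demethylase, and Zfp281.

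The array labelled TTF1 had 5 adjoining losses on chromosome 10 between 37822465 and 65179763, which deepened from -0.38 to -0.58. The last of them, from 56985059, held Tet1, which oxidises 5-methylcytosine. The same array had its largest absolute means over Nlgn1 on chromosome 3 (25419265 to 25452686, -1.15 ± 0.46), over Arhgap44 and Myocd on chromosome 11 (64822559 to 65079749, -0.96 ± 0.16) and over Ndufa10, Otos and 8 olfactory receptor genes on chromosome 1 (94271777 to 94777349, 0.95 ± 0.17). PF2 gained distal X, with a mean of 1.09 ± 0.35 from 155000626 to 166498497, a stretch with Rps6ka3 and Eif1ax that was singled out after its values were seen. Bcell4 had its longest autosomal gains on chromosome 5, the longest from 35836305 to 45630417 (0.27 ± 0.22). The same interval read 0.17 on Bcell2 and 0.00 on Bcell3. A chromosome 8 segment without an annotated protein-coding gene (15426531 to 15481545) was called both ways, at 1.82 ± 0.48 on PF1 and -1.94 ± 0.42 on TTF2. Skint4 on chromosome 4 (111760929 to 111831828) read 1.79 ± 0.78 on PF1 and -1.21 ± 0.47 on TTF2.

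At 1799 probes that were low on at least 3 of the 6 arrays off slide 2, the reference channel lay at -0.61 on PF1 and -1.71 on the array labelled TTF1 against the median of those 6 arrays, so the calls of both were read against a reference channel that differed from that of the other arrays. The test channel at these probes differed as well, at 0.39 on PF1 and -0.77 on the array labelled TTF1. It lay at 0.76 on TTF3 and 0.78 on the array labelled H2A.X-null, and between -0.19 and 0.50 on the remaining arrays. The number of called autosomal segments differed widely between lines. PF1 had 206 (119 Mb), PF2 164 (37.3 Mb), Bcell4 90 (74.4 Mb), TTF2 74 (100.3 Mb), Bcell2 73 (29.3 Mb), Bcell3 67 (76.5 Mb), the array labelled TTF1 34 (44.4 Mb) and TTF3 10 (4.13 Mb). These values, which the 4N comparison uses, do not count events, and inherited and acquired differences are mixed in them. The chromosome 11 gain of PF1 was divided into many called segments. Chromosome 11 of the array labelled TTF1 (median -0.22) stayed mostly under the limit of 0.25, and that array had 192.0 Mb at a limit of 0.15. The order of the lines by length depended on the scaling, since with normexp PF2 was the longest at 339.7 Mb, ahead of PF1 (271.8 Mb) and Bcell4 (246.2 Mb), and at a limit of 0.15 Bcell4 was the longest at 461.1 Mb. With the GC trend removed PF2 had 24.6 Mb. A segment was called at 10 or more probes and a mean of at least 0.25 in size. On simulated arrays with independent noise at the highest level, 13.2% of segments of size 0.3 over 15 probes and 99.5% over 100 probes were found. Short shallow changes were thus least visible on TTF2. The sum over the 8 lines was 718 segments and moved to 246 at a limit of 0.5 and 1294 at a limit of 0.15.

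**Figure D2:**
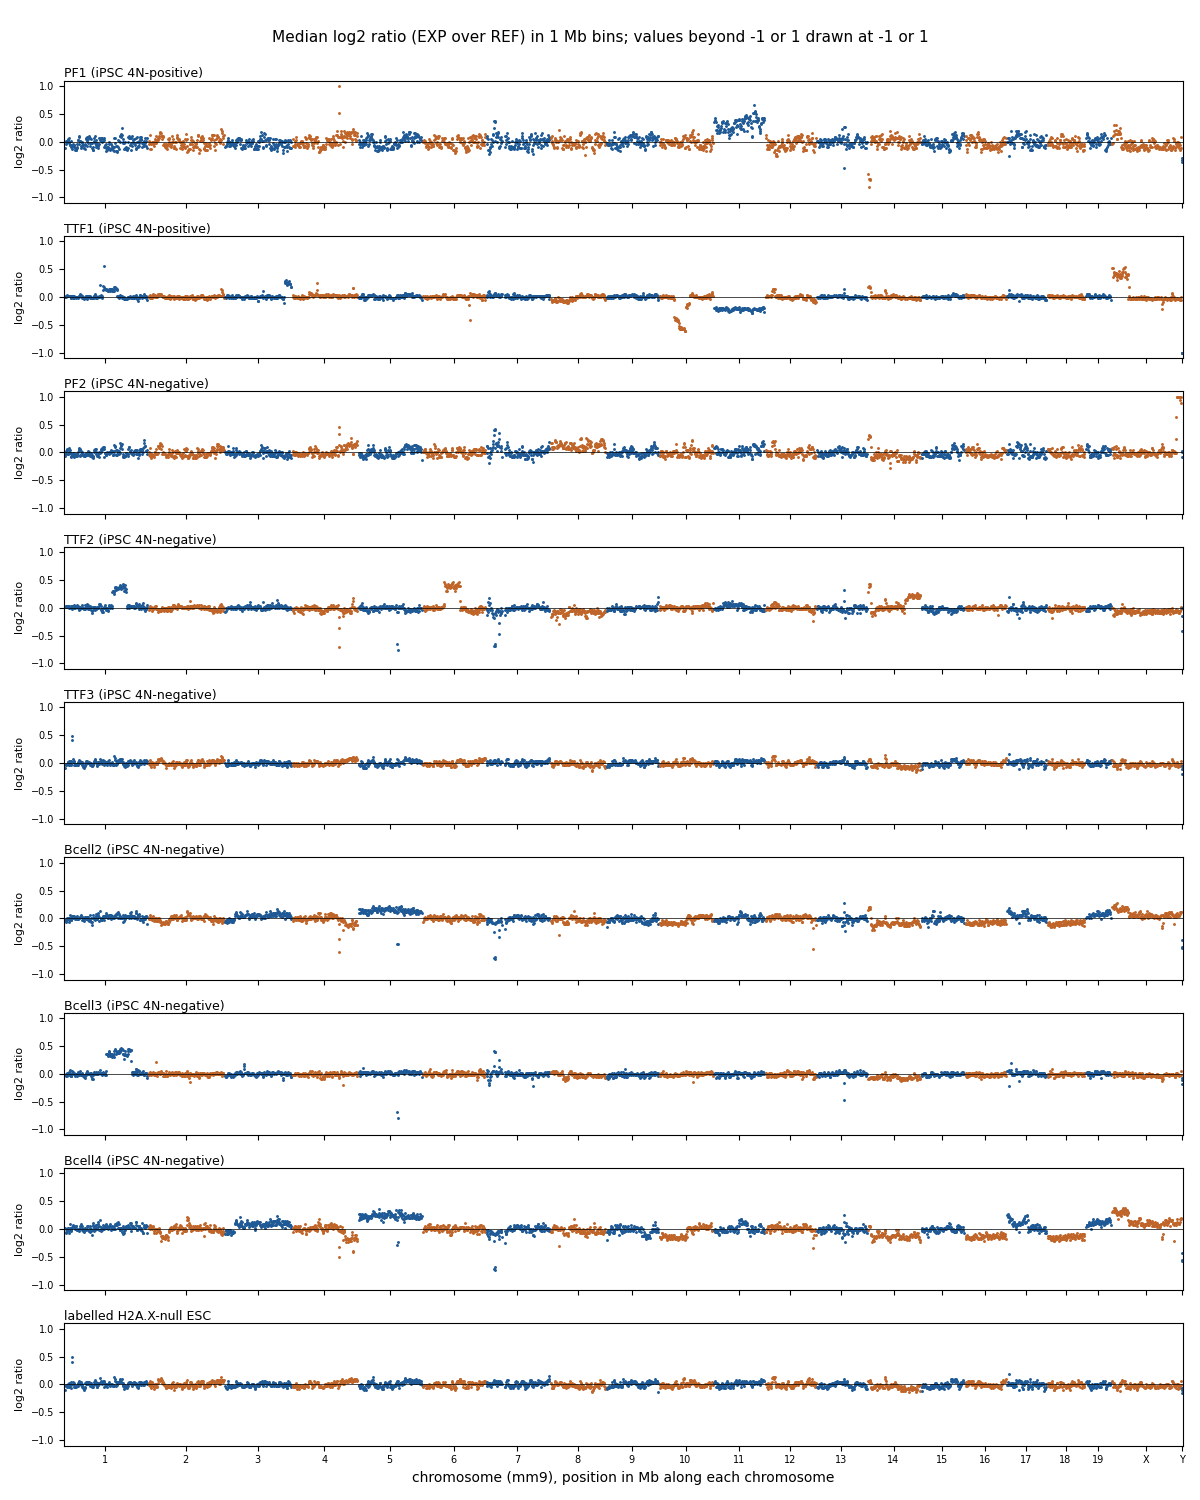
Median log2 ratio (EXP over REF) in 1 Mb bins along the chromosomes of build mm9 for each of the 9 arrays, with alternating colours for alternating chromosomes. The gain of chromosome 11 on PF1 (median 0.32), the losses on chromosome 10 of the array labelled TTF1, the chromosome 6 gain of TTF2 (0.38) and the chromosome 1 gains of TTF2 (0.34) and Bcell3 stand out from the flat traces of TTF3 and the array labelled H2A.X-null.

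Whole chromosomes were called at a median of at least 0.15 in size. Among autosomes, chromosome 11 read 0.32 on PF1 and -0.22 on the array labelled TTF1, and chromosome 5 read 0.24 on Bcell4. Chromosome 5 of Bcell2, at 0.14, stayed just under the limit, and that of Bcell3 was 0.02. Losses of Y were called on 5 arrays, at -0.33 on PF1, -1.55 on the array labelled TTF1, -0.22 on TTF2, -0.47 on Bcell2 and -0.51 on Bcell4. The unplaced Y sequence (Y_random) was called lost on 4 of them, at -0.40 on PF1, -2.55 on the array labelled TTF1, -0.56 on Bcell2 and -0.64 on Bcell4. The reference is male per the labels. Proximal X, from 3000121 to 40999929 and chosen after its values were seen, read 0.40 on the array labelled TTF1, 0.29 on Bcell4 and 0.18 on Bcell2, and between -0.07 and 0.06 on the other iPSC arrays.

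Some regions were called in several lines. Merging the calls of the 8 iPSC arrays gave 402 regions, of which 284 were called in 1 line, 82 in 2 or 3 lines and 36 in 4 or more. Both a gain call and a loss call lay in 48 of them, at times from the same line, as with Bcell3 on chromosome 12. A short call inside a long one was merged with it, so a line need not be changed over the whole region. The chromosome 6 region from 52811010 to 90491755 counted losses of the array labelled TTF1 and Bcell4, whose means over it were -0.002 and -0.004. No region was called in all 8. A loss on chromosome 17 from 30580034 to 31057733, over Btbd9, Glo1, which detoxifies methylglyoxal, Dnahc8 and Glp1r, was called in 7 lines and had its lowest mean on TTF2 (-0.49), while PF1 read 0.16. The labels give the iPSC arrays a shared reference, so a loss in the lines and a gain in the reference DNA cannot be told apart. PF1 is an array whose reference channel differed (-0.61), although the array labelled TTF1 (-1.71) read -0.26. The array labelled H2A.X-null, with another reference per its label, read -0.41. Nlrp1b on chromosome 11, an inflammasome sensor, was called in a loss in 6 lines (70988382 to 71164607). The means were -0.91 ± 0.76 on PF2 and -0.84 ± 0.69 on TTF2 (SD over 50 probes). They were -1.07 ± 0.95, -1.04 ± 0.88 and -1.06 ± 0.90 on Bcell2, Bcell3 and Bcell4, with -0.10 ± 0.41 on PF1 over the whole interval. These SDs exceed the probe-to-probe noise, so the probes of the interval were not evenly low. A vomeronasal receptor cluster on chromosome 7 (20648003 to 24119200, 48 listed Vmn1r genes) was gained in PF1 (0.35), PF2 (0.41) and Bcell3 (0.37) and lost in TTF2 (-0.67), Bcell2 (-0.73) and Bcell4 (-0.72). Cyp2b13 and Cyp2b9 on the same chromosome (26771203 to 26981472) were split in the same way, from 0.56 on PF2 to -1.45 on TTF2. The Tdpoz genes on chromosome 3 (93468201 to 94043298) were called in a gain in 6 lines, each over part of the interval, and the means over the whole interval were 0.26 on the array labelled TTF1, 0.19 on TTF2, 0.13 on Bcell4, 0.11 on PF2 and 0.08 on both PF1 and Bcell2.

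Of 11 gene lists fixed before the data were examined, 1 overlapped the merged regions more often than under 10000 circular shifts of the calls along the genome, after Benjamini-Hochberg adjustment over the lists. This was the list of copy number variable families, with 15 of 38 genes in called regions against a mean of 5.65 under shifts (permutation p = 0.0010, adjusted 0.0110). Its members included Glo1 and Nlrp1b, Skint3 (1.38 on PF1, -1.07 on TTF2), Defa3 (0.59 on PF1, -0.63 on Bcell4), Klra1 (0.47 on the array labelled TTF1) and Trim12a (-1.64 on PF1). Pluripotency and reprogramming genes came to 8 of 28 against 4.12 (permutation p = 0.0421, adjusted 0.232). Besides Stat3, Nr5a2 and Tet1, they were Klf4, at -0.26 on Bcell3, Klf2, at 0.28 on PF2, Zfp42 (Rex1), at 0.25 on PF2 and -0.29 on TTF2, and Dppa2 with Dppa4, at -0.25 on Bcell4. Vomeronasal receptors came to 126 of 326 against 47.4 (permutation p = 0.0687, adjusted 0.252).

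The other lists did not stand apart from shifted calls. DNA damage response and tumour suppressor genes came to 5 of 28 (adjusted permutation p = 0.886), which were Brca1, Trp53, Rad50 and, on chromosome 4, Cdkn2a with Cdkn2b (0.27), all gained on PF1. Histone and DNA modifying genes came to 2 of 20 (Suz12 and Kdm5b, 0.912), imprinted genes to 1 of 24 (Grb10, 0.33 on PF1 and -0.28 on the array labelled TTF1, adjusted p 0.912), and trophoblast genes to 1 of 16 (Hand1, 0.912). Fibroblast genes came to 1 of 12 (Col1a1, 0.912) and B cell genes to 1 of 13 (Cd79b, 0.912), both on PF1. Olfactory receptors came to 80 of 1106 (0.912) and zinc finger proteins to 64 of 358 (0.751).

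The second comparison was between 4N-positive and 4N-negative lines. The 2 4N-positive arrays did not share their main calls. Chromosome 11 was called gained on PF1 (0.32) and lost on the array labelled TTF1 (-0.22), and the Tet1 loss on chromosome 10 (-0.58 on the array labelled TTF1) had a value of 0.03 on PF1 and of -0.15 to 0.04 on the 4N-negative arrays. The 4N-positive arrays averaged 120.0 called segments (206 and 34) and the 4N-negative arrays 79.7 ± 49.6 (SD, n = 6), a difference of 40.3 (exact permutation test, two-sided, p = 0.536). The difference turned to -45.7 without PF1 and to -13.3 with normexp, and was 126.3 without the array labelled TTF1. Called length averaged 81.9 Mb against 53.7 ± 35.9 Mb (SD, n = 6, exact permutation p = 0.429), and that difference, 28.2 Mb, turned to -9.26 Mb without PF1 and was 65.7 Mb without the array labelled TTF1. At the main setting each slide that held both groups had the higher count on its 4N-positive array, 206 segments on PF1 against 164 on PF2 (119 and 37.3 Mb) and 34 on the array labelled TTF1 against 10 on TTF3 (44.4 and 4.13 Mb), and these pairs were not tested. On slide 1 the order turned at a limit of 0.15, with 333 segments on PF1 and 431 on PF2, and with normexp, with 173 and 519. With limma, 0 of 23980 bins of 100 kb passed an adjusted p of 0.05, and 857 had an unadjusted p under 0.05, where 1199 would be a 5% share. With slide as a block the counts were 0 and 619. Leaving out PF1 gave 239 bins past the threshold, 167 of them lower on chromosome 10 and 40 lower on chromosome 11, and leaving out the array labelled TTF1 gave 727, 624 of them higher on chromosome 11. Each of these fits has 1 array in the 4N-positive arm, which is assumed to vary like the 4N-negative lines, so its bins describe that array. At a segment limit of 0.5, PF1 (16.1 Mb) and the array labelled TTF1 (16.2 Mb) exceeded the 4N-negative arrays (0.738 to 9.63 Mb) with an exact permutation p of 0.0357, the smallest that 28 splits allow. These 2 arrays are also those whose reference channel differed (-0.61 and -1.71, against -0.06 to 0.08 on the 4N-negative arrays), so 4N group and reference cannot be told apart in this difference. The separation also rests on the label TTF1. The array labelled H2A.X-null had 0.731 Mb at this limit, so with these labels exchanged PF1 alone would exceed the 4N-negative arrays. Without the arrays labelled TTF1 and TTF3, a comparison added after the data were seen, the difference was 10.2 Mb against 11.1 Mb, and that design cannot go below an exact permutation p of 0.167.

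The third comparison set the 3 Bcell lines against the 5 TTF and PF lines, with the antigen receptor loci as the regions of interest because B cells delete DNA when they rearrange their immunoglobulin genes. All 3 Bcell lines are 4N-negative and share a slide that holds no other array. A segmentation of the difference of Bcell2 and Bcell4 called 4 segments, and 51 of the 73 calls of Bcell2 were shared with Bcell4. The tests here and in the 4N comparison count them as separate lines, so there may be fewer independent samples than given. Over the whole locus, Igh on chromosome 12 (114509484 to 117238672) averaged -0.30 ± 0.15 in the Bcell lines (SD, n = 3) and -0.13 ± 0.11 in the others (SD, n = 5; exact permutation p = 0.161, adjusted over 6 loci 0.241). Igl on chromosome 16 averaged -0.12 ± 0.07 against -0.01 ± 0.05 (exact permutation p = 0.0357, adjusted 0.107), and its flanks were low as well, at -0.12 on Bcell2, -0.02 on Bcell3 and -0.16 on Bcell4, which left 0.02, -0.05 and -0.04 for the locus minus its flanks. The median of the whole chromosome 16 was -0.07, -0.01 and -0.13 on these lines. The T cell receptor locus Tcrg averaged -0.08 ± 0.07 against 0.00 ± 0.04 (exact permutation p = 0.0357, adjusted 0.107). Its flanks read -0.030, -0.002 and -0.060 on Bcell2, Bcell3 and Bcell4 and 0.089 on PF1. The locus minus its flanks was -0.040, -0.016 and -0.088 on these Bcell lines, against -0.026 to -0.004 on the TTF and PF lines, which is a smaller gap. Igk, Tcra/Tcrd and Tcrb differed by -0.11, -0.09 and 0.04 (exact permutation p = 0.50, 0.429 and 0.143, adjusted 0.50, 0.50 and 0.241). No locus passed after adjustment, and a single locus could not go below 0.107. The flanks of Tcra/Tcrd on Bcell2, Bcell3 and Bcell4 read -0.14, -0.07 and -0.16, close to the locus itself (-0.15, -0.09 and -0.20). On PF2 that locus read -0.34 and its flanks -0.11, and without PF2 the Tcra/Tcrd difference was -0.16 (exact permutation p = 0.0286, adjusted 0.0571). Leaving out another line moved Igh to -0.09 (without Bcell2), Tcra/Tcrd to -0.05 (without PF1), Tcrb to 0.03 (without PF1) and Tcrg to -0.05 (without Bcell4). Igk read 0.37 on TTF2, inside the chromosome 6 gain of that array, and without the arrays labelled TTF1 and TTF2, a comparison added after the data were seen, its difference was -0.02.

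Across the autosomes limma found 0 bins past the threshold between Bcell and other lines, with 4176 at an unadjusted p under 0.05, where 1199 would be a 5% share. Bins are not independent of each other, and this excess was not tested. With slide as a random block there were 0 and 1957, and without the arrays labelled TTF1 and TTF2 there were 0 and 6214. Leaving out Bcell3 gave 831 bins, 528 of them higher on chromosome 5, where Bcell2 and Bcell4 read 0.14 and 0.24 and Bcell3 0.02. The Bcell arm of that fit is Bcell2 and Bcell4, whose difference held 4 called segments, so its bins may describe a pattern that these lines share.

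Inside Igh, the interval from the first J to the last D segment of the main cluster (chromosome 12, 114666725 to 114720403, 15 probes) was chosen after its values were seen. Its median was -1.60 on Bcell2, -2.07 on Bcell3 and -1.03 on Bcell4 (with normexp -1.999, -1.97 and -1.65). The array labelled TTF2 had the median of largest size, -2.46. These losses would be gains of the same size if the direction were turned, and the Bcell values were 1 of the reasons for the direction chosen. On the array labelled TTF2, 5 of 664154 autosomal stretches of 15 probes were as low. The interval read -0.24 on PF1, -0.09 on the array labelled TTF1, -0.11 on PF2, 0.04 on TTF3 and 0.09 on the array labelled H2A.X-null. Between the D cluster and the first V gene the medians were -1.45 on Bcell2, -0.74 on Bcell4, -0.71 on TTF2 and -0.12 on Bcell3. Over the V genes nearest to D (114812453 to 115297696) they were -1.37 on Bcell2, -0.45 on Bcell4, -0.38 on TTF2 and -0.03 on Bcell3. The constant region side of the J segments stayed between -0.18 and 0.05 on all 9 arrays.

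**Figure D3:**
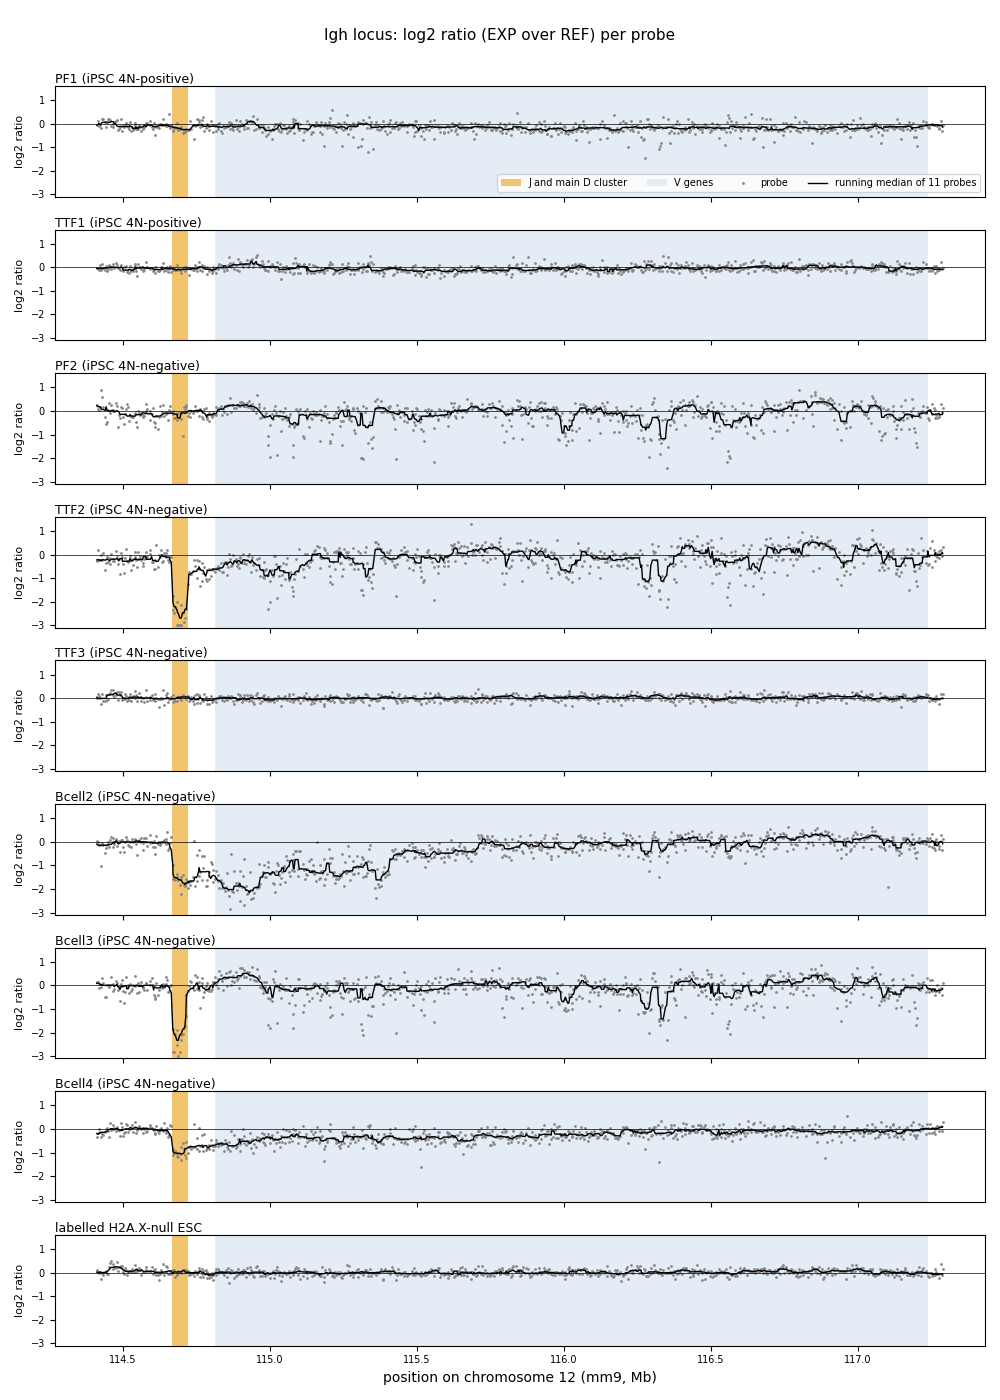
Log2 ratio (EXP over REF) of each probe along the Igh locus on chromosome 12 in Mb, 1 panel per array, with a running median of 11 probes as a line, the J and main D cluster in orange and the V genes in pale blue. The J to D interval drops to medians of -1.03 to -2.07 on the 3 Bcell arrays and to -2.46 on the array labelled TTF2.

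The fourth comparison, H2A.X-null against floxed ESC DNA, rests on 1 array and on its label. The array labelled H2A.X-null had 15 called autosomal segments (9 gains and 6 losses, 4.61 Mb). The one with most probes was a gain on chromosome 1 from 18632179 to 21272034 (0.43 ± 0.18, SD over 722 probes) over Tcfap2d, Tcfap2b and Pkhd1, the gene mutated in recessive polycystic kidney disease. The same interval read 0.44 ± 0.17 on TTF3 and between -0.10 and 0.02 on the other arrays. The Glo1 loss on chromosome 17 read -0.41 on the array labelled H2A.X-null and -0.41 on TTF3. Further calls lay over Vmn2r20 to Vmn2r22 on chromosome 6 (0.28), Colec12, Thoc1 and Usp14 on chromosome 18 (0.32), Srp54b, Srp54a and Fam177a on chromosome 12 (0.29), Zfp932 on chromosome 5 (0.36) and Cyp2a22 on chromosome 7 (-0.25). Gain or loss was not called over any whole chromosome of this array. The correlation of this array with TTF3 across probes, which are not independent replicates, was 0.75, 8 of the 10 calls of TTF3 were shared, and a segmentation of the difference of both arrays called 2 segments (0.105 Mb), against 4 to 305 for other pairs. The lowest of these, 4, was that of Bcell2 and Bcell4, and the median of the other pairs was 97. At a segment limit of 0.5 the array labelled H2A.X-null had 1 called segment.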

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

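The tests of a flaw around the spot, of the likeness of the arrays labelled TTF3 and H2A.X-null, of the Igh haplotype, of an exchange with a Bcell line, of a T cell history, of the slide and of dilution were chosen only after the result was seen. Among the 6 4N-negative lines, 32 quantities were searched for a line far from the others by Dixon's ratio, which singles out about 1 in 20 by chance, and 3 were found. The median of chromosome 6 was 0.055 on TTF2, against -0.006 to 0.011 on the other lines. The mean over Igk was 0.374 on TTF2 and at most -0.017 on the others, and this locus lies inside the chromosome 6 gain of TTF2. The median of chromosome 8 was 0.115 on PF2 and at most -0.017 on the others.

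The probe beside H2afx read -2.54 on the array labelled TTF1 and 0.06 on the array labelled H2A.X-null. A flaw of the array surface that covers more than the spot was argued against by the lowest of the 8 nearest spots, -0.23 (the lowest of the 81 spots around it, -3.33, was a Y_random probe), and a flaw of this spot alone was not excluded. At 1799 probes that were low on at least 3 of the 6 arrays off slide 2, the reference channel was set against those 6 arrays. It lay at -1.712 on the array labelled TTF1 (bootstrap interval -1.76 to -1.65) and at 0.00 on the array labelled H2A.X-null. The bootstrap resampled the probes of 1 array, which are not independent, so its interval gives no spread between arrays. These values go with labels exchanged between these arrays and a reference of 129/Sv background on the array labelled TTF1, although PF1 also lay at -0.61. The test channel at these probes lay at -0.77 on the array labelled TTF1, so the difference of that array was not confined to its reference channel. The difference between the arrays labelled TTF3 and H2A.X-null held 2 called segments, fewer than any other pair, which argues against the different DNA pairs that their labels give. The next pair, Bcell2 and Bcell4, held 4 although these arrays carry different labels, and the median of the other pairs was 97. The scan names in the file headers go with the labels, so an exchange would have to lie before the naming of the scans, and a true change beside H2afx in the line TTF1 was not excluded, and the titles of all samples begin with H2AX without saying whether an iPSC line came from H2A.X-targeted cells.

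The J to D interval of Igh had a median of -2.46 on the array labelled TTF2, of larger size than on any Bcell array. A shared strain haplotype of Igh was argued against by PF2, at -0.113. An exchange with a Bcell line was argued against because the highest of the 3 Bcell medians was -1.03. A T cell history that left receptor losses of 5 probes or more was argued against by the lowest median of 5 neighbouring probes in Tcra/Tcrd and Tcrb on that array, -0.319, where the same measure in Igh was -1.13 or lower on the Bcell arrays, although a low value would not have shown a rearrangement, since PF2 read -1.98 in Igh and -1.32 in Tcra/Tcrd and Bcell4 -0.63 in Tcra/Tcrd (the mean over a locus, the measure chosen first, was dropped because it was only -0.175 for Igh on Bcell3). A single wrong label, or a B cell origin of the line labelled TTF2, may account for the loss, and both stay open.

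Bcell2 and Bcell4 shared their pattern of chromosome medians, with r = 0.996 over 19 autosomes, which are not independent replicates (permutation p = 1e-05, the smallest that the permutations can give), and Bcell4 had 1.65 times the shifts of Bcell2. The slide was argued against by Bcell3 on the same slide, with a chromosome 5 median of 0.018. Waves with GC content were argued against by the chromosome 5 median of Bcell4 after removal of the GC trend, 0.239. Dilution of the Bcell4 culture with unchanged cells was argued against by the J to D interval, which was lower in Bcell2 than in Bcell4 by a difference of -0.567 (-1.60 against -1.03, and with normexp -1.999 against -1.65, a difference of -0.345). Related cultures that share changes in part of their cells may account for the pattern, which was not tested.

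For the Bcell comparison of bins, the real split of the 8 lines into 3 and 5 had 0 bins past the threshold with limma and 4176 at an unadjusted p under 0.05, so 56 of 56 splits had as many by necessity, and this count bears on nothing. The highest other split had 77 bins and set TTF2, Bcell2 and Bcell4 apart.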

How the results depend on the processing

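The fits without the arrays labelled TTF1 and TTF3, or TTF1 and TTF2, and the other scalings of the J to D interval and of the probe beside H2afx were chosen only after the result was seen. The total of 718 called segments became 1294 at a limit of 0.15, 246 at a limit of 0.5, 379 with penalty 50 and 1471 with runs of 100 kb bins, and called length became 1613 Mb, 62.5 Mb (limit 0.5) and 1410 Mb (normexp). The 4N difference in segments (40.3) turned to -13.3 with normexp, where PF2 had 519 segments, and the difference in length was 11.1 Mb at a limit of 0.5 (exact permutation p = 0.0357, the smallest possible). Leaving out each line moved the 4N difference in segments from -45.7 (without PF1) to 126.3 (without the array labelled TTF1) and in length from -9.26 Mb (without PF1) to 65.7 Mb (without the array labelled TTF1). Bins past the threshold with limma ran from 0 to 727 for 4N, with 239 without PF1, 727 without the array labelled TTF1 and 475 without the arrays labelled TTF1 and TTF3, and from 0 to 831 for Bcell, with 831 without Bcell3 and 0 without the arrays labelled TTF1 and TTF2. The array labelled H2A.X-null had 1 segment at a limit of 0.5, 23 at 0.15, 26 with at least 5 probes, 9 with at least 20 and 9 with penalty 50, against 15. A higher or lower limit on the mean or the number of probes changes these counts by construction, and for the other moves the cause was not tested.

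The lowest adjusted exact permutation p of a receptor locus under the alternatives was 0.0571 (Igl, Tcra/Tcrd and Tcrg without PF2), which says little about stability, since a single locus could not pass after adjustment in any of these designs. Leaving out each line gave differences of -0.23 to -0.09 for Igh, -0.14 to -0.02 for Igk, -0.14 to -0.08 for Igl, -0.16 to -0.05 for Tcra/Tcrd, 0.03 to 0.05 for Tcrb and -0.11 to -0.05 for Tcrg, and without the arrays labelled TTF1 and TTF2 they were -0.18, -0.02, -0.09, -0.06, 0.06 and -0.09 in this order. The number of whole-chromosome calls did not move past 1.5 times with the mean over all probes, nor did the number of merged regions with any overlap (388). These were the only alternatives tried for them, apart from the series value table, which is identical to the values used. The count of whole-chromosome calls was not repeated with loess, normexp or the GC trend removed, so this says little about stability. Of 54 values of the J to D interval and of the probe beside H2afx, 10 moved by more than the spread used for them, all with normexp, where the probe read -0.89 on the array labelled TTF1 and 1.26 on Bcell2. Of 90 segment counts per line and setting, 38 moved by over 1.5 times, and of 90 called lengths 24 did. Both totals include the series value table, where no value could move because that table is identical to the values used. No paired analysis was possible from the replicate numbers, which name lines, and with slide as a block limma gave 0 bins past the threshold for 4N and 619 at an unadjusted p under 0.05. Noise limits short segments of small size, most on TTF2 (0.209).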

Other observations

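No test in this part was chosen only after the result was seen, and the values carry no explanation. In single lines, copy number variable families overlapped calls more often than under shifts on TTF2 (adjusted permutation p = 0.0011), Bcell2 (0.0011), the array labelled TTF1 (0.0022), Bcell4 (0.0055), Bcell3 (0.0231), PF2 (0.0275), TTF3 (0.0473) and the array labelled H2A.X-null (0.0495), and not on PF1 (0.207). On TTF3 and on the array labelled H2A.X-null the overlap was 3 genes, Btbd9, Glo1 and Dnahc8, in 1 call on chromosome 17, so it rests on that call alone. The same 3 genes in the same loss also counted on TTF2, Bcell2, the array labelled TTF1, Bcell4, Bcell3 and PF2. The overlaps of these arrays are therefore not separate support for each other. Vomeronasal receptors overlapped calls more often than under shifts on PF2 (adjusted permutation p = 0.0275) and Bcell2 (0.0077). The chromosome 7 cluster call alone held 48 and 42 listed genes on these arrays, against 59 and 50 vomeronasal receptors in calls. Most of this overlap thus rests on that cluster. The adjustment was over the lists within each array and not across arrays. Itln1, which encodes intelectin 1, lay in a loss on TTF2 (-0.68), Bcell3 (-0.63) and Bcell2 (-0.40), Ifi203 in a loss on the same lines (-0.33, -0.46 and -0.33), and Naip5, a sensor of bacterial flagellin, in a gain on TTF2 (0.42) and Bcell2 (0.33). Stfa1 on chromosome 16 (36237218 to 36320279) read -1.004 ± 0.67 on Bcell2, -0.92 ± 0.61 on PF2 and -0.79 ± 0.66 on TTF2 (SD over 25 probes). It read -0.99 ± 0.64 on Bcell3 and -0.99 ± 0.57 on Bcell4, against -0.08 on PF1, 0.04 on the array labelled TTF1 and 0.01 on TTF3. With such SDs the probes were not evenly low.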
